A study of Mus musculus with 7 samples.

How the data were processed

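RNA was measured in Beta-TC6 cells, an insulin-secreting line established from a mouse pancreatic beta-cell tumour. Per the labels, all 7 samples were wild type, 3 were treated with IL1B (interleukin-1 beta, an inflammatory cytokine) and 4 with vehicle. Per the labels' protocols, cells grew in DMEM with 15% fetal bovine serum and were synchronised with a 1 h pulse of 10 µM forskolin, a drug that raises cAMP; polyadenylated RNA was made into libraries with the NEBNext Ultra II kit. The dose and duration of the IL1B treatment, the time of harvest after the pulse, the read length and the strand setting are not given in the sources used here.

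The authors deposited 1 table of raw counts per gene symbol, with 23329 symbols and 7 columns of whole numbers. Per the submitters' processing notes, reads of the whole study were handled against the mouse build mm10, and the tools named are STAR, RSEM, HOMER, Bowtie2, DESeq2, Cell Ranger, Seurat, Signac and R 4.1.0, without roles. Which of them aligned and counted these reads, which annotation was used and how reads matching several genes were counted are not given in the sources used here. Counts of near-identical copies are therefore uncertain. Among the 112 named genes tested, Abhd15, Atp5c1, Cfb and Jund share at least 30% of their longest transcript at 95% identity or more with another annotated transcript (blastn 2.17.0), and members of the H2 and Gbp families and the pair Ins1 and Ins2 are related paralogs. Also, 9 tested genes, in 4 sets, have the same counts in all 7 libraries as another gene, and none of the named genes is among them.

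Column names of the vehicle group match the sample titles 1 to 4. The table numbers its IL1B columns 1, 2 and 3 while the titles number the IL1B samples 1, 3 and 4. The IL1B columns were therefore assigned to the group only, and the numbers of IL1B libraries used here are the table's own. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of libraries within a group agreed within sampling noise: the chi-square per degree of freedom ran from 1.53 to 4.93 over 9 pairs, and all 7 were kept as separate replicates.

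Total counts ran from 5335607 to 7513934 per library, and 3 counts, the floor used for genes with no count, equal 0.399 to 0.562 counts per 1e6 of these totals. CPM below are counts per 1e6 counts in tested genes, after TMM scaling. Intervals and floors cover counting error only. Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, the filterByExpr rule, which left 12480 genes, and the quasi-likelihood F test of IL1B against vehicle over all 7 libraries with no covariate. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Fold changes are given as log2 values with standard errors (the absolute log2 fold change over the square root of F), and levels as mean CPM ± SD. For genes with 0 counts in the vehicle group the fold is a lower bound against 3 counts over that group, and with 1 to 3 counts it is the ratio of summed counts over summed scaled library sizes with an exact 95% interval.

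The 24 gene lists, the tests and the rule for naming genes were fixed before the data were examined. The rule takes the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, up to 4 members of each list with the smallest adjusted p, and 18 genes fixed by name. Lists with at least 3 tested members, 20 of the 24, were tested with fry (limma 3.58.1) on log2 CPM with a prior count of 2, adjusted over the lists. Fry tests whether a list's genes move, on balance, one way and does not compare the list with other genes. Of 491 list symbols, 489 were found in the table, some under older symbols (9630033F20Rik for Tigar, Ero1lb for Ero1b, Mycl1 for Mycl). Coordinates are those of GRCm38, the same assembly as mm10, from the GENCODE annotation; 22831 symbols (97.9%) had 1 gene model.

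On counts simulated for 12382 genes from these libraries' means and sizes, with 200 genes changed, the edgeR test recovered 71.4% of 77 tested genes changed 1.5-fold, 91.2% of 57 changed 2-fold and 98.4% of 62 changed 4-fold, with 3.45% false calls. The simulated changes went up or down at random in genes of at least 1 CPM, with no library set apart. In the data 1374 genes changed, mostly upward, and 2 libraries stood apart, so these rates may not carry over. Alternatives were RLE, upper-quartile and total-count scaling, no low-count filter, a minimum of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, camera with a preset correlation of 0.01 or an estimated one, and leaving out each library in turn. A correction for GC content and transcript length, and a fit without the second vehicle and second IL1B libraries, were chosen after seeing the data.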

Results

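The series measured the transcriptome of Beta-TC6 mouse beta cells treated with IL1B (n = 3 libraries) or vehicle (n = 4) and synchronised with a forskolin pulse, which aligns the cells' circadian clocks. Vehicle libraries held 5335607 to 7513934 counts and IL1B libraries 6007723 to 6969745. Ins2, the more abundant insulin transcript, took 1.99% to 2.34% of all counts, and the 10 most abundant genes together 5.60% to 6.18%. The first principal component of log2 CPM carried 57.1% of the variance and separated the groups. The second vehicle library stood apart within its group: over genes, its deviation from the vehicle mean correlated with transcript length at a Spearman rho of -0.54, against 0.21 to 0.30 in the other vehicle libraries (genes are not independent replicates). The second IL1B library also stood apart: its chi-square per degree of freedom was 4.21 and 2.90 against the other IL1B libraries, which gave 1.72 between them. The series title names NF-kB and circadian enhancers, and the comparison asks which transcripts IL1B moved in these cells.

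IL1B raised a broad set of inflammatory transcripts, led by chemokines, adhesion molecules and the NF-kB system's own genes, and lowered a smaller set, mostly by less than 2-fold (394 of 406 genes). Most increases were also below 2-fold (722 of 968 genes). Of 12480 genes tested, 968 rose and 406 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Among changes of at least 2-fold, 246 were increases and 12 decreases, and 3 of the 12, Gm14430, Gm14434 and Gm4724 (named after their values were seen), have identical counts in every library and the largest fitted decrease, 7.38-fold. The count of 2-fold decreases was 23 without IL1B library 1, 24 with no low-count filter and 7 with DESeq2. Groups did not overlap in 1333 of the 1374 changed genes and in 21.0% of all tested genes, against 5.71% by chance. With total-count scaling, 844 genes rose and 556 fell (60.3% increases against 70.5%). Without IL1B library 3, 252 genes fell, and without the second library of each group, a setting chosen after seeing the data, 676 fell.

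Cytokines and chemokines, secreted proteins that signal to or attract leukocytes, were among the largest increases. Cxcl1 (chromosome 5, 90891241 to 90893115) had 2 counts over the 4 vehicle libraries and 3140 over the 3 IL1B libraries, a ratio of 2090 (95% counting interval 578 to 17268), and reached 167 ± 2.25 CPM (SD, n = 3). Its neighbour Cxcl2 had no vehicle count and was at least 133-fold higher with IL1B. Tnf, an inflammatory cytokine, rose from 2 counts to 363 (ratio 242, 66.4 to 2003), and the monocyte attractant Ccl2 from 2 to 355 (ratio 236, 64.9 to 1959). Cxcl10 rose from 2.64 ± 1.07 to 121 ± 18.5 CPM, and Csf1, the macrophage growth factor, 20.2-fold (log2 fold change 4.33, SE 0.07, edgeR adjusted p = 5.6e-19). Of 15 measured cytokines and chemokines, 11 rose and none fell (12 rose adjusted over the list alone; fry adjusted p = 6.7e-07). Another 13 genes of this list stayed below the filter, among them Il6, with 0 vehicle and 5 IL1B counts. Cxcl1, Cxcl2, Tnf and Ccl2 passed the filter through their IL1B counts alone, so they could not have been called lower.

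Genes of the NF-kB pathway, the transcription factor system that IL-1 receptors switch on, rose almost as a block: 16 of 18 measured members rose and none fell (18 adjusted over the list alone; fry adjusted p = 6.8e-08). Nfkbia, which encodes the inhibitor IkBa and lies on chromosome 12 (55489410 to 55492647), rose 15.4-fold, from 31.1 ± 1.49 to 479 ± 18.4 CPM (log2 fold change 3.94, SE 0.07, edgeR adjusted p = 5.6e-19). Tnfaip3, which encodes the feedback inhibitor A20, rose 17.7-fold and Nfkbiz, an atypical IkB protein, 27.7-fold. The subunit genes Nfkb2 and Relb rose 11.2-fold and 10.8-fold, and Birc3, a ubiquitin ligase of the pathway, 46.3-fold. Upstream, 2 of 15 measured IL-1 receptor signalling genes rose, and the list as a whole did not pass (2 adjusted over the list alone; fry adjusted p = 0.10). These were the adaptor Myd88, 1.54-fold, and the receptor Il1r1, 1.19-fold (edgeR adjusted p = 0.0167), whose call was lost without IL1B library 1 (adjusted p = 0.0515) or 3 (adjusted p = 0.0991); its second vehicle library, at 242 CPM, lay below the other 3 (289 to 291). The list passed over all 7 libraries with a minimum of 1 CPM in 3 libraries (fry adjusted p = 0.0108), and also without the second vehicle library (fry adjusted p = 0.0165) or without IL1B library 3 (fry adjusted p = 0.0256).

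**Figure D1:**
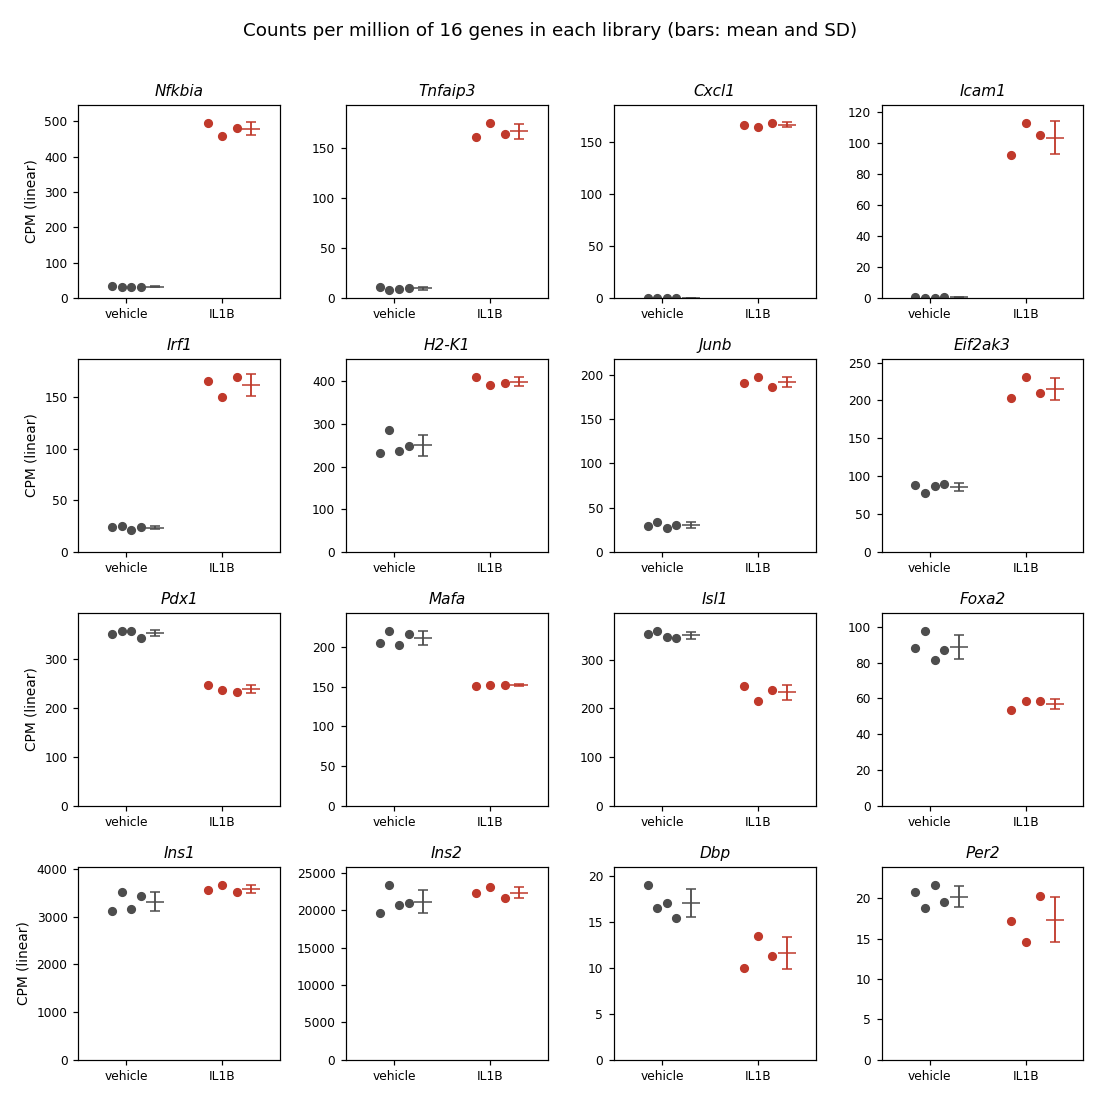
CPM (linear axes from 0) of 16 genes in the 4 vehicle and 3 IL1B libraries, 1 point per library, with the group mean and SD beside the points. Nfkbia rose from 31.1 to 479 CPM and Pdx1 fell from 354 to 240 CPM with no overlap, while the groups overlap for Ins1, Ins2 and Per2.

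Adhesion and matrix genes, interferon-stimulated genes and antigen presentation genes also rose. Icam1, the leukocyte adhesion molecule on chromosome 9 (21015985 to 21028817), went from 0.288 ± 0.185 to 103 ± 10.5 CPM (log2 fold change 8.43, SE 0.19, edgeR adjusted p = 2.6e-17). Sele, which encodes E-selectin, went from 1 count to 191 (ratio 254, 45.1 to 10096). Both genes passed the filter through their IL1B counts alone, so they could not have been called lower. Another 11 genes of the adhesion and matrix list stayed below the filter. Of 10 measured genes in that list 5 rose and none fell (5 adjusted over the list alone; fry adjusted p = 3.7e-05). Among interferon-stimulated genes 8 of 22 rose and none fell (9 adjusted over the list alone; fry adjusted p = 3.7e-05), with Irf1, an NF-kB and STAT target, at 6.86-fold, Gbp3 at 24.8-fold and Gbp5 at 33.8-fold. Of the 16 measured antigen presentation genes 6 rose (6 adjusted over the list alone; fry adjusted p = 3.5e-04): the class I heavy chain H2-K1 rose from 250 ± 24.3 to 399 ± 10.5 CPM, H2-D1 1.39-fold and Tapbp, which encodes the peptide-loading factor tapasin, 1.80-fold. Only 1 of 15 acute phase and complement genes in the table passed the filter, Cfb, which rose 7.36-fold and shares 81.7% of its transcript with another annotated gene.

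Stress-related lists rose as well. Of 24 immediate early and cAMP-responsive genes, 13 rose and 1 fell (17 and 3 adjusted over the list alone; fry adjusted p = 3.4e-05). Junb rose 6.36-fold, Jun 3.21-fold and Ier3 10.8-fold, while the orphan nuclear receptor Nr4a2 fell 1.84-fold. In the unfolded protein response 8 of 24 genes rose and none fell (8 adjusted over the list alone; fry adjusted p = 7.7e-05). Eif2ak3, which encodes the stress kinase PERK, rose 2.51-fold (log2 fold change 1.33, SE 0.07, edgeR adjusted p = 2.4e-11), Trib3 2.17-fold, Chac1 2.03-fold and the transcription factor Atf4 1.48-fold. The other 16 genes of this list, among them Xbp1, Hspa5, Hsp90b1, Pdia4 and Hyou1, did not pass, and the list's median log2 fold change was 0.105. Of 21 apoptosis genes 6 rose and none fell (6 adjusted over the list alone; fry adjusted p = 3.0e-04). They included the death-promoting Bbc3 (2.12-fold) and Bid (8.50 to 17.0 CPM), and also Birc2 (1.41-fold), an inhibitor of cell death.

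Transcription factors that maintain beta-cell identity fell on balance: of 19 measured, 11 fell (12 adjusted over the list alone; fry adjusted p = 0.0011). The falls ran from 1.19-fold to 1.59-fold. Pdx1 lies on chromosome 5 (147269959 to 147275848) and encodes a regulator of the insulin genes. It went from 354 ± 6.40 to 240 ± 7.96 CPM (log2 fold change -0.56, SE 0.05, edgeR adjusted p = 3.0e-07). Isl1 fell from 351 ± 7.13 to 233 ± 15.4 CPM, Foxa2 1.56-fold and Mafa 1.39-fold.

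The insulin transcripts did not pass the threshold. Ins1 stood at 3309 ± 198 CPM with vehicle and 3581 ± 78.2 with IL1B (edgeR adjusted p = 0.196), and Ins2 at 21183 ± 1599 and 22372 ± 715 (edgeR adjusted p = 0.416). Both were higher past the threshold without the second vehicle library, whose transcript-length trend is given above (edgeR adjusted p = 0.0305 for Ins1 and 0.0274 for Ins2). Among 25 measured genes of insulin production and glucose sensing 2 rose and 2 fell (6 and 3 adjusted over the list alone; fry adjusted p = 0.157), and the list's median (0.02) and mean (-0.0036) differ in sign. Kcnj11, a subunit of the ATP-sensitive potassium channel, rose 1.48-fold and the endoplasmic reticulum oxidase gene Ero1lb 1.15-fold, while the fatty acid receptor Ffar1 fell 1.82-fold and the incretin receptor Glp1r 1.27-fold. Glp1r lost its call without vehicle library 1 or 4 or IL1B library 1 or 3 (edgeR adjusted p 0.0950 to 0.143). The glucose transporter Slc2a2 had a log2 fold change of -0.15 (SE 0.09, edgeR adjusted p = 0.343). Of 26 exocytosis genes 2 rose and 3 fell (3 and 4 adjusted over the list alone; fry adjusted p = 0.157), with Stx3 1.48-fold higher and Syt13 1.27-fold lower, and the list passed downward with total-count scaling (fry adjusted p = 0.0424).

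Most core clock genes did not pass the threshold, while Nr1d2 and Bhlhe41 did. Arntl (log2 fold change 0.17, SE 0.16), Clock (-0.06, SE 0.07), Nr1d1 (0.18, SE 0.17), Per1 (0.08, SE 0.10), Per2 (-0.22, SE 0.12) and Cry1 (0.03, SE 0.08) did not pass, with edgeR adjusted p from 0.292 to 0.869. Of 19 measured clock and clock-output genes 2 rose and 2 fell, and the list had no net direction (2 and 3 adjusted over the list alone; fry adjusted p = 0.780). Dbp, a clock output factor, fell 1.48-fold (edgeR adjusted p = 0.0061) and lost its call without IL1B library 1 (adjusted p = 0.0518). Nr1d2, a clock repressor, rose 1.24-fold. Bhlhe41 rose 1.53-fold, a call lost without IL1B library 2 (adjusted p = 0.0812), and Tef fell 1.21-fold, a call lost without vehicle library 1 or 4 or IL1B library 1 or 3 (adjusted p 0.0835 to 0.154) and with DESeq2 over all 7 libraries (adjusted p = 0.0779). The time of harvest is not given in the sources used here, so phase cannot be read from these values.

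**Figure D2:**
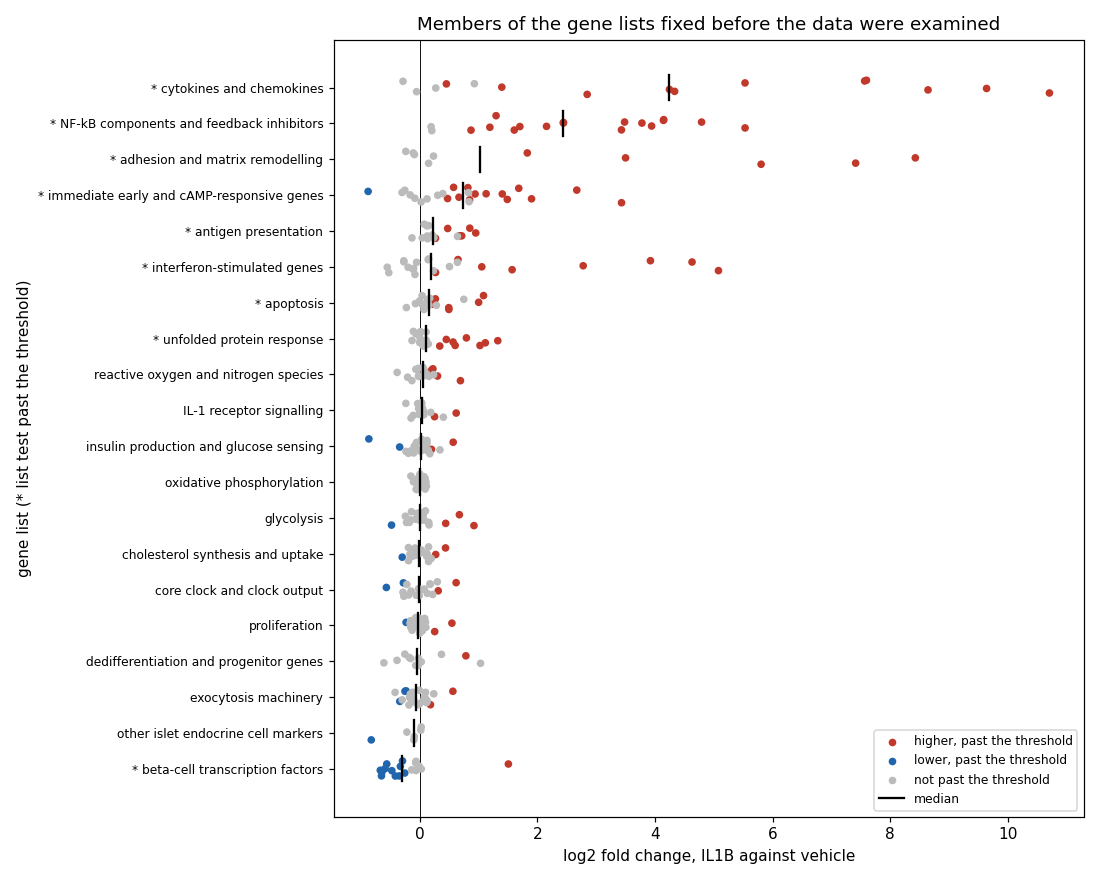
Log2 fold changes (IL1B against vehicle) of the measured members of 20 gene lists, 1 point per gene with vertical jitter, red or blue where the gene rose or fell past the threshold and grey otherwise; black bars mark medians and an asterisk a list past its test. The 9 lists past the test include 8 shifted up and the beta-cell transcription factors, shifted down.

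Metabolic and growth lists did not pass with TMM scaling. None of 26 oxidative phosphorylation genes passed by edgeR, DESeq2 or limma-voom, or at an unadjusted edgeR p under 0.05 (fry adjusted p = 0.871), 3 of 20 glycolysis genes rose and 1 fell (0.641), and 2 of 20 cholesterol genes rose and 1 fell (0.641); adjusted over the list alone, these counts were the same. The glycolysis and cholesterol medians (-0.0034 and -0.0056) and means (0.05 and 0.01) differ in sign. The glycolysis genes that rose were Hk1 (1.59-fold), Pfkfb3 (1.89-fold) and Eno2 (1.36-fold). In the proliferation list 2 of 26 rose and 1 fell (2 and 2 adjusted over the list alone; fry adjusted p = 0.157), with the cell cycle inhibitor Cdkn1a 1.46-fold higher, and the list passed downward with total-count scaling (fry adjusted p = 0.0017). Of 12 dedifferentiation genes 1 rose by edgeR, Myc, 1.72-fold (2 adjusted over the list alone; fry adjusted p = 0.641). Mycl1 also passed with limma-voom (adjusted p = 0.0451) and, by edgeR, without the second vehicle library (adjusted p = 0.0261), and the list's median (-0.05) and mean (0.04) differ in sign. Of 17 genes handling reactive oxygen and nitrogen species 4 rose (4 higher and 1 lower adjusted over the list alone; fry adjusted p = 0.110), with Hmox1 1.61-fold higher, and the list passed without the second vehicle library (fry adjusted p = 3.4e-04). Sod2 was at 142 ± 8.16 and 148 ± 6.27 CPM (edgeR adjusted p = 0.693), and Nos2, the inducible nitric oxide synthase, stayed below the filter with 1 vehicle count and 10 IL1B counts (ratio 13.3, 1.89 to 578).

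Among markers of other cell types Irx2 passed by edgeR with TMM scaling. Gcg, which encodes glucagon, had a log2 fold change of -0.22 (SE 0.08, edgeR adjusted p = 0.0887) and passed downward with total-count scaling (adjusted p = 0.0443), with no low-count filter (0.0075) and without IL1B library 1 (0.0234). Of 6 measured markers of other islet endocrine cells 1 fell, Irx2, and none rose (0 and 2 adjusted over the list alone; fry adjusted p = 0.100), and the list passed downward with total-count scaling (fry adjusted p = 0.0424). Of the leukocyte, stromal and exocrine or duct lists 1, 1 and 2 genes passed the filter (Cd68, Col1a2, Spp1 and Krt7), with means of 1.70, 3.11, 15.8 and 5.50 CPM in vehicle, and none passed by edgeR (adjusted p from 0.574 to 0.926), DESeq2 or limma-voom, or at an unadjusted edgeR p under 0.05. The largest decreases past the naming rule were in Slitrk6 (2.33-fold, 92.5 ± 7.09 to 39.6 ± 8.13 CPM), Nhsl2 (2.13-fold), Bambi, a decoy receptor of TGF-beta signalling (2.12-fold), and Abhd15 (2.11-fold), which shares 33.3% of its transcript with another annotated gene. The 9 lists past the test also passed with camera at an estimated correlation, where their adjusted p ran up to 0.0365. In the lists past the test that held no falling gene by edgeR, DESeq2 and limma-voom gave none either, nor did an unadjusted edgeR p under 0.05. Genes nearly absent in vehicle passed the filter through the IL1B group alone and could not be called lower. The absence of falling genes in these lists therefore rests in part on the filter.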

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

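The tests of library scaling and of beta-cell number, and the correction for GC content and transcript length, were chosen after the result was seen.

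The split into IL1B and vehicle gave 1374 changed genes by edgeR, and the highest of the other splits of the 7 libraries gave 1. Only 1 of the 35 splits, the labelled one, gave as many, the smallest share these splits can give. Every other split puts IL1B and vehicle libraries in the same set, which adds the IL1B difference to the spread within sets. Low counts there therefore do not measure chance differences between cultures, and the splits do not exclude chance.

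Among the vehicle libraries, 12 of 118 groups of values held a library far from the other 3 by Dixon's test, where chance gives about 1 in 20 (5.9). The second vehicle library gave 7 of them. Ribosomal protein genes took 3.78% of its counts, against 3.20% to 3.29% in the others, and its correlation of expression deviation with transcript length was -0.537, against 0.211 to 0.297. Its CPM stood apart for Il1r1 (241.93, others 289 to 291), Lrrc17 (12.2, others 15.5 to 15.97), Bid (10.96, others 7.40 to 7.98), Tnf (0.313, others 0) and Sele (0.157, others 0). The first vehicle library stood apart for Slitrk6 (103.1 CPM, others 88.4 to 90.04), Jun (58.1, others 54.5 to 55.0) and Ccl2 (0.263, others 0). The third stood apart for Nr1d1 (10.6 CPM, others 7.64 to 7.83) and the fourth for Spp1 (14.5, others 16.1 to 16.4). The values of Tnf, Sele and Ccl2 rest on 1 or 2 counts.

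Changes of at least 2-fold were nearly all increases, 246 of 258. The lowest share of increases over the 3 other scalings was 94.6%. Those scalings put the median log2 fold change of all tested genes at -0.010 to -0.041, against -0.0087 with TMM. Shifts so small could hardly turn 2-fold changes around, so this comparison cannot decide whether scaling was the cause. The tables argue against low counts that hide decreases, since among genes of at least 20 CPM in vehicle 63 of 66 such changes (95.5%) were increases. After each library's trend with GC content and transcript length was removed the share was 95.3%, which argues against such bias. An induction by IL1B may account for the lean towards increases, as a hypothesis that these tests do not settle.

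Pdx1 and 10 other beta-cell transcription factors fell while Ins1 and Ins2 did not pass and had higher means with IL1B. A lower share of beta cells, or RNA from other cells, would lower abundant beta-cell products alike, but the median log2 fold change was -0.29 for the 19 factors and 0.02 for the 25 genes of insulin production and glucose sensing (two-sided permutation p = 0.00052, 100000 resamples). The difference between these lists was seen before the test, and the permutation treats genes as independent. Its p therefore only describes the difference seen. Removing the GC and length trends left 112% of the median fall of the 11 factors, and all 11 stayed past the threshold. A lower output of these factor genes with IL1B may therefore be a response of the beta cells themselves, as a hypothesis; whether insulin mRNA falls at other times stays open, since other times were not tested here.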

How the results depend on the processing

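The GC and length correction and the fit without the second library of each group were chosen after seeing the data. No paired analysis was possible because the IL1B columns cannot be matched to the numbered samples, so the replicate block fits were not run. Changed genes numbered 1021 (without IL1B library 3) to 1847 (without both second libraries) over the alternatives, against 1374, and no gene of the 1374 changed sign in any of them. Counts of decreases moved by over 1.5 times. Falling genes numbered 252 to 589 over single libraries left out and 676 without both second libraries, against 406. Decreases of at least 2-fold numbered 10 to 23 over single libraries left out (23 without IL1B library 1), 24 with no low-count filter and 7 with DESeq2, against 12; the cause was not tested. DESeq2 gave 833 higher and 278 lower genes, limma-voom 960 and 386, and the GC and length correction 1153 and 541. Of 84 named genes past the threshold, 71 kept their call in every alternative and 13 lost it in some, 10 of these only when a library was left out; 6 of the 28 others passed in some. Lists were rerun with total-count scaling, the 1 CPM filter, camera, single libraries left out and both second libraries left out; in these all 9 lists past the test stayed past it, and 5 of the other 11 passed in some: IL-1 receptor signalling, reactive species and, downward with total-count scaling, exocytosis (adjusted p = 0.0424), proliferation (0.0017) and other islet endocrine markers (0.0424). In the simulation 71.4% of 1.5-fold changes were recovered, and smaller ones were not simulated.

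Signs changed for 5 named genes and 6 lists, none of them past the threshold. On the log2 scale, Sst was -0.0015 with upper-quartile and -0.0079 with total-count scaling, and -0.011 to 0.078 over single libraries left out. That range was -0.30 to 0.36 for Cd68, -0.18 to 0.11 for Krt7 and -0.011 to 0.083 for Cry1. Without both second libraries Ttr was 0.012 and Krt7 0.15. Lists that turned direction, none past its test, did so with total-count scaling for insulin production (adjusted p = 0.906), dedifferentiation (0.988), oxidative phosphorylation (0.828) and cholesterol (0.929), with camera for dedifferentiation (0.952 preset, 0.977 estimated), and without both second libraries for cholesterol (0.781). Over single libraries left out the adjusted p ran from 0.374 to 0.975 for the clock, 0.301 to 0.881 for dedifferentiation, 0.394 to 0.759 for glycolysis, 0.0997 to 0.975 for oxidative phosphorylation and 0.394 to 0.880 for cholesterol. The cause of these was not tested.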

Other observations

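The tests of neighbouring genes that leave out gene copies or use gene order, and the family counts in the next paragraph, were chosen after the data were seen.

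Of 199 families of genes sharing a symbol root with at least 8 tested members, 2 passed for a larger share of rising genes than the 7.76% of all tested genes (Fisher's exact test, one-sided, Benjamini-Hochberg over families and directions). Of genes whose symbols have the root Il, mostly interleukins and their receptors but also the amino-acid oxidase gene Il4i1, 9 of 20 rose (adjusted p = 0.0030), among them the receptor subunit genes Il6st (1.58-fold), Il10rb (2.23-fold), Il18rap (10.1-fold) and Il13ra1 (2.14-fold) and the cytokines Il15 (19.0-fold, from 0.174 to 3.36 CPM) and Il23a (5.61-fold). In the Kruppel-like factors 6 of 13 rose (adjusted p = 0.0455): Klf5 (2.35-fold), Klf6 (1.59-fold), Klf7 (4.07 to 8.36 CPM), Klf9 (1.49-fold), Klf10 (1.47-fold) and Klf11 (2.02-fold). These genes were named after their values were seen, and Il1r1, Il15 and Klf6 also belong to the lists above.

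Rising genes lay next to one another more often than their number gives: 88 pairs of neighbouring tested genes within 100 kb both rose, against 49.1 ± 6.74 (SD) when calls were permuted within bins of expression (one-sided permutation p = 0.0001, the smallest 10000 permutations can give). By orientation, only same-strand pairs passed, 54 against 24.5 with copies included (one-sided permutation p = 0.0001). Convergent pairs, 17 against 11.9 (one-sided permutation p = 0.0905), and divergent pairs, given below, did not. Examples, chosen after their values were seen, are Cxcl1 with Cxcl2, Icam1 with Icam5 (3.36-fold), and the receptor genes Il10rb, Ifnar1 (1.23-fold) and Ifngr2 (4.19-fold) on chromosome 16. Gene copies alone are argued against, since pairs with no shared symbol root and no blastn match between their transcripts numbered 75 against 45.6 (one-sided permutation p = 0.0001, likewise the smallest); copies too diverged for blastn, possibly the receptor genes above, are not left out. Read-through from an induced neighbour as the whole cause of the same-strand pairs was argued against, because the upstream gene had the larger rise in 35.7% of 42 such pairs that are not copies (exact 95% interval 21.6% to 52.0%), where a constant read-through share gives the downstream gene the smaller one; for the 15 pairs with the larger upstream rise it stays open. Read-through in part cannot be told apart from shared regulation, since divergent pairs, 17 against 12.6, did not pass (permutation p = 0.132); shared enhancers within a neighbourhood may contribute, and no enhancer data were used here.

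Falling genes gave no such excess past the threshold: 13 neighbouring pairs both fell, against 8.60 ± 2.89 (one-sided permutation p = 0.0937).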
